A study of Arabidopsis thaliana with 4 samples.

How the data were processed

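RNA-seq was used to measure transcript levels in callus grown from Arabidopsis thaliana hypocotyls. Callus is a mass of dividing cells that forms when explants are kept on callus induction medium (CIM), which holds an auxin and a cytokinin. Per the labels' protocols, seedlings were grown in darkness for 9 days, hypocotyl pieces of about 1 cm were placed on CIM with 11 µM of the synthetic auxin 2,4-D, 0.2 µM kinetin and 2% sucrose at 22 °C, and about 100 calli went into each RNA sample. The protocols give 5 to 6 days on CIM and the stage label gives 6 days. The 4 libraries fall into 2 groups of 2 by their genotype label, wild type (accession Col-0) and the plt1 plt2 double mutant. The labels do not say that the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

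The deposited table holds raw read counts per gene, with 1 column per library. Per the submitters' processing notes, Trim Galore 0.5.0, STAR 2.7.2b, DESeq2 and the genome build TAIR10 were used. The counting tool, the gene annotation and whether strand was used were not given in the sources used here, and neither were the mutant alleles. Without stated strand use, reads of overlapping or antisense genes cannot be told apart. The counts were used as deposited. The table held 23922 loci, each with at least 1 read in some library, and no columns of other samples. Locus codes were matched to symbols and descriptions in the RefSeq annotation of TAIR10.1, and 23755 matched. Coordinates are from TAIR10.1, since the count table gives none. The totals were 59049542 and 57254672 reads in the libraries labelled wild type 1 and 2, and 63209401 and 53907649 in those labelled plt1 plt2 1 and 2. In simulated libraries with the means, sizes and dispersions of these 4 (19151 genes), the test recovered 62% of genes changed 1.25-fold, 88% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold, 50 genes each, and 10 of its 202 calls were false. A list planted with a 1.5-fold decrease was called in the same simulation, and 0 of 23 lists without a change were. Genes were simulated independently of each other with the trended dispersions, and changed genes were drawn from those with a mean of 20 or more reads. The simulation therefore does not show how often lists of co-regulated genes are called falsely, or the recovery of genes with fewer reads. It also leaves out differences in dispersion between genes of like abundance, so its recovery and share of false calls may be too favourable. The family and position tests were also tested on simulated calls: 1 family was enriched over 19325 genes, the planted one. Those calls were drawn independently for each gene, so related genes called together were not covered.

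Differential expression was tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by genotype, glmQLFit and glmQLFTest with genotype as the only term, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05, with no minimum fold. Adjusted p values of single genes are from this test unless another tool is named. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Positive values mean higher in the libraries labelled plt1 plt2. CPM values, which express the counts of a gene relative to its library total, were computed from the deposited counts with TMM-scaled library sizes. Where both libraries of a genotype held 0 reads, a fold is a lower bound against a floor of 3 counts over the group, 0.0254 CPM for the libraries labelled plt1 plt2. With 1 to 3 reads the ratio is given with its exact 95% interval. Both cover counting error only.

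Before the data were examined, 26 gene lists with 371 members were fixed, together with the tests, the alternatives and the rule for named genes; 299 members were tested, and 27 had no row and were not analysed here. Lists with 3 or more tested members (24) were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and adjustment over the lists. Each was also tested with an estimated correlation, and with fry, which asks whether the members move one way on balance. Members are also counted with p adjusted over the list alone. Enrichment of 31 families, found by keywords in the reference descriptions, was tested per direction with one-sided Fisher's exact tests against all tested genes with a description, for families with 5 or more tested members and with adjustment over the 62 tests. The share of called genes within 2 Mb of PLT1 or PLT2 was compared with that of the other nuclear genes by a two-sided Fisher's exact test.

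The named genes are PLT1 and PLT2; the 12 largest increases and 12 largest decreases among called nuclear genes with a symbol, a mean of 20 or more reads per library and no overlap between the genotypes in CPM; of each list, up to 4 called members with the largest change, or the 2 with the smallest p where none was called; WOX5, SCR, SHR, TAA1, LBD16, PLT3, PLT5, PLT7, BBM, ARR5 and ARR7 always; and of each enriched family the 3 called members with the largest change. This gave 147 genes. Of these, 32 overlap another gene in the reference, 26 of them on the other strand, and 10 have 10% or more of their exon bases in BLAST+ 2.17.0 matches elsewhere with an exact seed of 50 bases. Their counts are uncertain, and those the report names are marked there.

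Alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2 (RLE), no filter, a mean of 50 or more reads per library, a replicate block, each library left out in turn, other thresholds, glmTreat against a fold of 1.5, organelle genes left out, other windows and other call sets. A fit without 1 library leaves 1 library in a group, which is then assumed to vary like the other group. Chosen after seeing the data were a crossed pairing, the check of overlaps and matches elsewhere, the PLT/AIL list without PLT1 and PLT2, the AP2/ERF keyword without B3 descriptions, and lists of sugar starvation, indole glucosinolate and aliphatic glucosinolate genes.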

Results

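Transcript levels were compared between hypocotyl-derived callus labelled wild type and callus labelled plt1 plt2 after about 6 days on callus induction medium, with 2 libraries per label. PLT1 and PLT2 encode AP2-type transcription factors of the PLETHORA/AINTEGUMENTA-LIKE (PLT/AIL) family, known for maintaining the root stem cell niche. Sequencing depth ranged from 53907649 to 63209401 counted reads per library. The most abundant gene, HSC70-1, took between 0.579% and 0.591% of the reads of each library, and mitochondrial genes took at most 0.0149%. The 2 libraries of a label differed by more than sampling noise (chi-square per degree of freedom of 5.35 for wild type and 7.75 for plt1 plt2) and by less than libraries of different labels (21.03 to 25.52), and each was counted as its own sample, as labelled. The first principal component held 67.6% of the variance and separated the labels.

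The disrupted genes were examined first. PLT1 (AT3G20840; TAIR10.1 chromosome 3, 7300444 to 7303693, plus strand, 9 distinct exons) had 171 and 166 CPM in the libraries labelled wild type and 122 and 128 CPM in those labelled plt1 plt2, a log2 fold change of -0.43 ± 0.05 (SE; edgeR adjusted p = 0.000181). PLT2 (AT1G51190; chromosome 1, 18977176 to 18980618, plus strand, 9 distinct exons) had 63.1 and 62.1 CPM in the libraries labelled wild type and 182 and 179 CPM in those labelled plt1 plt2, a log2 fold change of 1.53 ± 0.04 (edgeR adjusted p = 3.37e-08). Reads of PLT2 were thus 2.88-fold higher under the label that names its disruption. Counts per gene cannot show where in a gene the reads lie, and a disrupted gene can still be transcribed, so these counts do not settle the genotype, and the libraries are called by their labels throughout. Every direction given here rests on those labels.

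**Figure D1:**
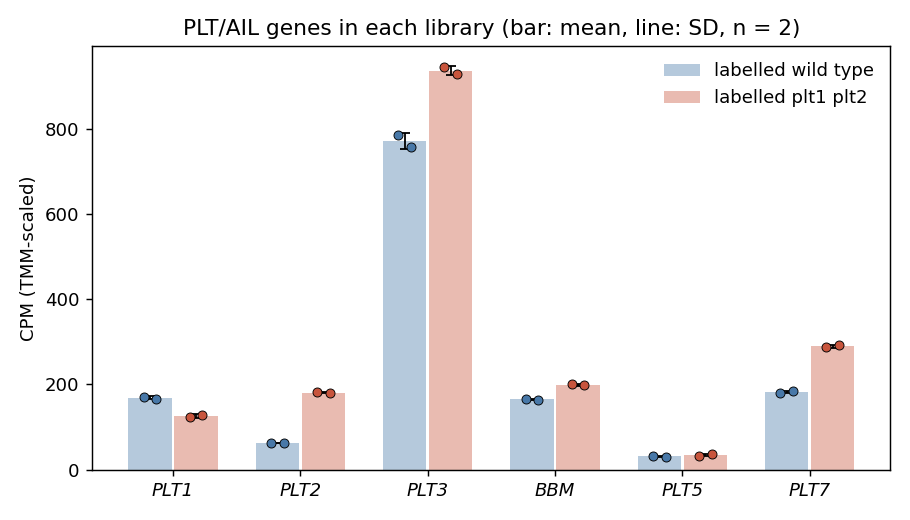
TMM-scaled CPM (vertical axis) of 6 PLT/AIL genes in the 2 libraries labelled wild type (blue) and the 2 labelled plt1 plt2 (red), with bars for means, lines for the SD (n = 2) and points for libraries. PLT1 lay at 171 and 166 CPM against 122 and 128 CPM, and PLT2 at 63.1 and 62.1 CPM against 182 and 179 CPM.

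Among the other PLT/AIL genes, PLT7 rose from 182 ± 2.84 to 289 ± 2.80 CPM (mean ± SD, n = 2; log2 fold change 0.67 ± 0.04 SE), PLT3 from 770 ± 19.0 to 936 ± 10.8 CPM (0.28 ± 0.04) and BBM from 165 ± 1.55 to 199 ± 1.78 CPM (0.27 ± 0.04). PLT5 had a log2 fold change of 0.16 and was not called (edgeR adjusted p = 0.168), except without the library labelled plt1 plt2 1 (0.0132). Of 7 tested members, 4 rose, PLT2 among them, and PLT1 fell; adjusted over the list alone, 5 rose and 1 fell. The list was called upward by camera (adjusted p = 9.47e-12), with an adjusted p = 0.214 with an estimated correlation. Without PLT1 and PLT2, an alternative chosen after seeing the data, the 5 remaining members gave an unadjusted camera p of 9.87e-07, and 0.0379 with an estimated correlation. The unadjusted camera p values of the full list were smaller, 7.89e-13 and 0.0179, so leaving out PLT1 and PLT2 did not strengthen the result. The call of PLT3, which overlaps a gene on the other strand, ended without the library labelled wild type 2 (adjusted p = 0.0534).

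Across the transcriptome, 2027 of 19325 tested genes (10.5%) differed between the labels, 894 higher and 1133 lower in the libraries labelled plt1 plt2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Most changes were small: 1322 of the called genes changed less than 1.5-fold, while 103 rose and 257 fell by 2-fold or more. Both libraries of 1 label lay above both of the other for 54.7% of tested genes, where chance gives 33.3%. The same held for all 2027 called genes, which follows largely from the test that called them. The count was 1137 without the library labelled wild type 1 and 1068 without wild type 2. With a test against a fold of 1.5 (glmTreat), 198 genes were called, 44 higher and 154 lower.

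**Figure D2:**
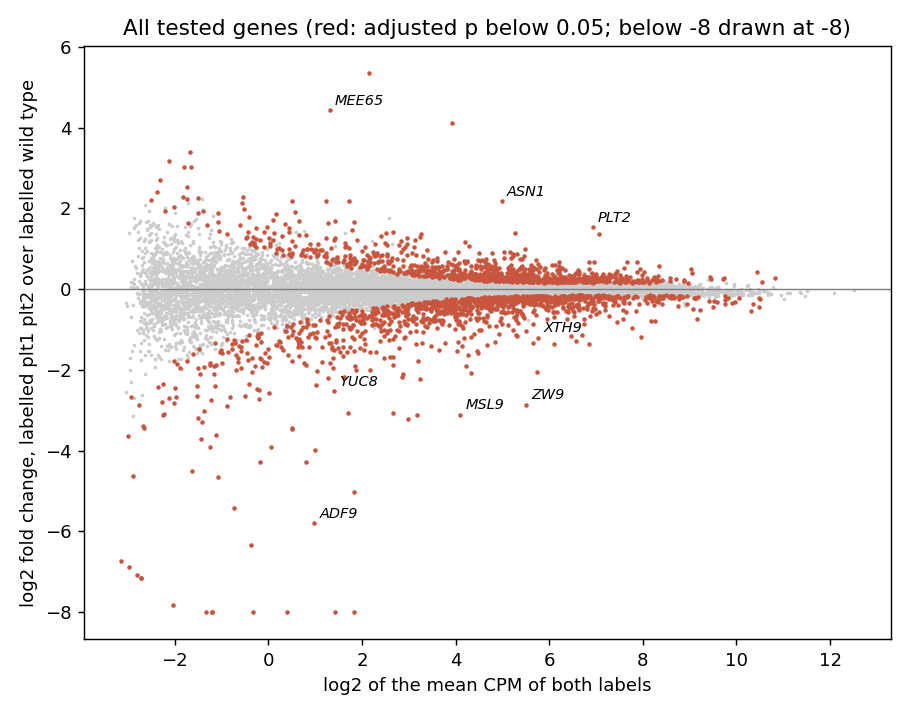
Log2 fold change between the libraries labelled plt1 plt2 and those labelled wild type (vertical axis; values beyond its range are drawn at its lower edge) against the log2 of the mean CPM of both labels (horizontal axis), with 1 point per tested gene and called genes in red. Of 19325 genes, 894 were called higher and 1133 lower.

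The 12 largest increases included ASN1 and MEE65. ASN1, an asparagine synthetase, had 9.15 and 13.8 CPM in the libraries labelled wild type and 66.2 and 37.2 CPM in those labelled plt1 plt2 (log2 fold change 2.18 ± 0.24, edgeR adjusted p = 0.000263). GAT1_2.1 (2.19), the branched-chain amino acid transaminase BCAT-2 (1.69), the dark-inducible gene SEN1 (1.85), NADP-ME1 (1.68) and the myo-inositol oxygenase MIOX4 (1.58) also rose. MEE65 rose from 0.216 ± 0.0325 to 4.73 ± 0.272 CPM (log2 fold change 4.43 ± 0.23), and COR15A (2.27), AGL96 (1.90), OFP4 (1.90), scpl2 (1.67) and PLT2 completed the 12. MEE65, GAT1_2.1, ASN1 and BCAT-2 overlap genes on the other strand, scpl2 overlaps a gene on its own strand, and 91.3% of the exon bases of scpl2 lie in matches elsewhere in the genome, so these counts are uncertain. The calls of OFP4, scpl2 and MIOX4 ended without the library labelled wild type 1 (adjusted p = 0.0653, 0.164 and 0.164), and those of OFP4 and scpl2 also without wild type 2 (0.252 and 0.0688), that of OFP4 without plt1 plt2 2 (0.0926), and those of OFP4 (0.0705) and scpl2 (0.0511) by DESeq2.

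The 12 largest decreases included MYB34 and YUC3. MYB34, a regulator of indole glucosinolate synthesis, had 349 and 266 reads in the libraries labelled wild type and 0 in both labelled plt1 plt2, at least 210-fold lower (edgeR adjusted p = 2.35e-06). YUC3, a flavin monooxygenase of auxin synthesis, had 173 and 131 reads against 0, at least 104-fold lower (adjusted p = 1.67e-05). UGT71B8 fell to 2 reads in both libraries together, a ratio of 90.6 (95% interval 24.7 to 754). ADF9 (log2 fold change -5.80), MGP (-3.92), RGF3 (-3.70), APL4 (-3.46), RGF1 (-3.20), MSL9 (-3.11), ZW9 (-2.86), NAC094 (-2.67) and ZPR3 (-2.64) made up the rest of the 12. ZW9 was the most abundant of these, at 80.0 CPM in the libraries labelled wild type and 11.0 CPM in those labelled plt1 plt2. APL4 and MSL9 overlap genes on the other strand. In all, 13 called genes had 0 reads in both libraries labelled plt1 plt2, and 0 had none in both labelled wild type.

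Most auxin biosynthesis genes tested were lower. Of 8 tested members, 6 fell and 0 rose, and the same counts held adjusted over the list alone. TAA1, which makes indole-3-pyruvate, fell from 16.1 ± 0.220 to 6.03 ± 1.41 CPM (log2 fold change -1.41 ± 0.13, edgeR adjusted p = 6.65e-05), YUC8 from 4.49 ± 0.0156 to 0.778 ± 0.0378 CPM (-2.52 ± 0.18), and CYP79B3, which makes indole-3-acetaldoxime, from 2.68 to 0.992 CPM (-1.43 ± 0.20). YUC3, TAR2 and CYP79B2 were the other called members, and TAR2 and CYP79B2 are named here after their values were seen. The median log2 fold change was -1.32, the same with YUC3 at its bound, and camera called the list downward (adjusted p = 4.22e-12), with an adjusted p = 0.214 with an estimated correlation. In the same libraries root cap markers had a list median of -0.73, and phloem markers, a list that was not called (camera adjusted p = 0.0535), had one of -0.52.

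Genes of the root founder cell and root stem cell niche list split. Of 20 tested members 2 rose and 9 fell (5 rose and 11 fell adjusted over the list alone), with a median log2 fold change of -0.22. The zinc finger genes MGP (-3.92 ± 0.50) and NUC (-1.69 ± 0.20) and the root meristem growth factor genes RGF3 (-3.70 ± 0.57) and RGF1 (-3.20 ± 0.52) fell most; MGP, RGF1 and RGF3 were below 1 CPM in every library. SCR fell from 274 to 212 CPM (-0.37 ± 0.05). WOX5, a marker of the quiescent centre, rose from 138 ± 7.26 to 158 ± 6.06 CPM (0.19 ± 0.05, edgeR adjusted p = 0.0375), a call that ended without the library labelled wild type 1 (adjusted p = 0.242), without plt1 plt2 1 (0.0604) and with a replicate block (0.0578). SHR had a log2 fold change of -0.09 and was not called (edgeR adjusted p = 0.247). Camera called the list downward (adjusted p = 0.000377), with an adjusted p = 0.425 with an estimated correlation.

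Most root cap genes tested were lower. Of 7 tested members 5 fell and 0 rose, and adjusted over the list alone 5 fell and 1 rose. The NAC genes FEZ (log2 fold change -1.17 ± 0.13), BRN2 (-0.93 ± 0.21), BRN1 (-0.90 ± 0.15) and SMB (-0.73 ± 0.14), which control root cap cell maturation and division, all fell, BRN1 from 44.8 to 24.2 CPM. The calls of BRN2 (adjusted p = 0.0889) and SMB (0.0927) ended without the library labelled wild type 1, that of BRN2 also without wild type 2 (0.123), and DESeq2 did not call BRN1 (0.0714). Camera called the list downward (adjusted p = 0.000693), with an adjusted p = 0.425 with an estimated correlation, and fry did not (adjusted p = 0.0916).

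**Figure D3:**
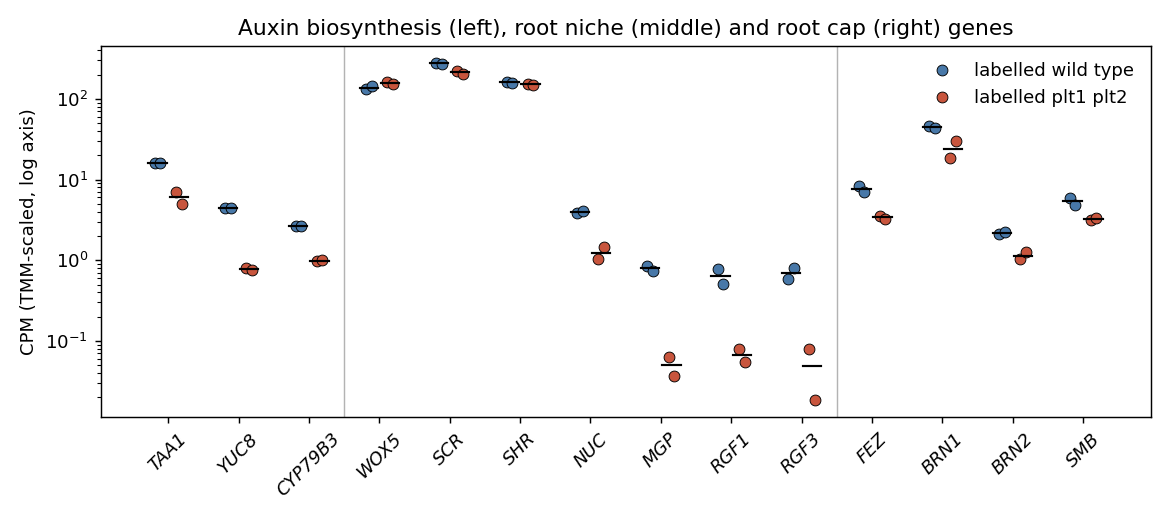
TMM-scaled CPM on a log axis of auxin biosynthesis genes (left), root niche genes (middle) and root cap genes (right), with 1 point per library (blue, labelled wild type; red, labelled plt1 plt2) and a line for each mean (n = 2). TAA1 lay at 16.1 against 6.03 CPM and YUC8 at 4.49 against 0.778 CPM, while WOX5 lay at 138 against 158 CPM.

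Auxin response genes rose more often than they fell. Of 24 tested members 8 rose and 1 fell (10 and 3 adjusted over the list alone). IAA29 (log2 fold change 0.86 ± 0.16), IAA11 (0.58 ± 0.06) and GH3.1, which encodes an auxin-conjugating enzyme (0.56 ± 0.04, from 263 to 388 CPM), rose, and IAA28 fell (-0.75 ± 0.12). IAA11 overlaps a gene on the other strand, and the call of IAA29 ended without the library labelled wild type 2 (adjusted p = 0.0643). Camera called the list upward (adjusted p = 0.000377), with an adjusted p = 0.378 with an estimated correlation. Auxin transport genes went both ways, 4 higher and 5 lower of 16 (6 and 6 adjusted over the list alone). PIN2 fell from 27.9 to 12.3 CPM (-1.18 ± 0.09), LAX2 from 113 to 71.7 CPM (-0.66 ± 0.04) and the kinase gene WAG1 by 0.93 on the log2 scale, while PIN7 rose from 435 to 614 CPM (0.50 ± 0.04). The WAG1 call ended by DESeq2 (adjusted p = 0.0591) and without wild type 1 (0.123), wild type 2 (0.148) or plt1 plt2 2 (0.0697). The median of this list was 0.06 and its mean -0.16, and camera pointed downward without calling it (adjusted p = 0.361).

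Genes of lateral root and callus initiation were not called as a list (camera adjusted p = 0.356), though 6 of 14 rose and 2 fell (6 and 3 adjusted over the list alone). LBD33 (log2 fold change 1.01 ± 0.18), LBD17 (0.49 ± 0.12), LBD16 (0.28 ± 0.06, from 125 to 151 CPM) and ARF19 (0.28 ± 0.06, overlapping a gene on its own strand) rose, and WIND2 fell (-0.42 ± 0.05). The calls of LBD16 (adjusted p = 0.112) and LBD17 (0.0788) ended without wild type 1, those of LBD16 (0.0514), LBD17 (0.190) and ARF19 (0.135) without wild type 2, and that of LBD17 also without plt1 plt2 1 (0.0900). Of 6 tested shoot meristem and regeneration genes 3 rose and 1 fell, and the same counts held adjusted over the list alone: KNAT1 (0.40 ± 0.04, from 105 to 138 CPM), KNAT6 (0.38 ± 0.05) and RAP2.6L (0.30 ± 0.05) rose and CUC2 fell (-0.19 ± 0.05). Camera called this list upward (adjusted p = 0.0227), with an adjusted p = 0.443 with an estimated correlation, 0.0791 without wild type 1 and 0.0572 without a filter on low counts. The CUC2 call ended by DESeq2 (adjusted p = 0.115), with a replicate block (0.0578) and without wild type 1 (0.0687), wild type 2 (0.278) or plt1 plt2 1 (0.0762). Of the embryogenic regulators, with 2 tested members, 1 called (2 rose adjusted over the list alone) and no set test, LEC1 rose (log2 fold change 2.22 ± 0.53) at 0.105 against 0.494 CPM, and its call ended without wild type 1 (adjusted p = 0.180).

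Cytokinin genes moved both ways. Of the type-A response regulators 1 of 7 rose and 2 fell (1 and 4 adjusted over the list alone): ARR3 (log2 fold change -0.65 ± 0.13) and ARR8 (-0.27 ± 0.07) fell and ARR9 rose (0.19 ± 0.05), and the calls of all 3 ended without wild type 1 (adjusted p = 0.0641, 0.149 and 0.273). Without wild type 2 the calls of ARR3 (0.0810) and ARR8 (0.0817) ended as well, and that of ARR8 also without plt1 plt2 2 (0.0984) and by DESeq2 (0.0734). ARR5 (-0.28, adjusted p = 0.114, and 0.00397 without plt1 plt2 2) and ARR7 (0.26, adjusted p = 0.574) were not called by edgeR, and the list was not called by camera (adjusted p = 0.292). Of 23 other cytokinin genes 7 rose and 5 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.527). The synthesis gene IPT5 (0.90 ± 0.13) and the oxidase gene CKX7 (0.54 ± 0.14) rose, and CKX5 (-0.73 ± 0.06) and LOG4 (-0.47 ± 0.09) fell. The calls of CKX7 (adjusted p = 0.111) and LOG4 (0.0799) ended without wild type 1, and that of CKX7 also without wild type 2 (0.198), without plt1 plt2 2 (0.0858) and by DESeq2 (0.0739). ARR8, ARR9, CKX5 and LOG4 overlap genes on the other strand, and 28.5% of the exon bases of ARR8 lie in matches elsewhere.

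Few cell division genes were called. Among 20 genes of the mitotic cell cycle 0 rose and 2 fell (0 and 4 adjusted over the list alone), AUR2 (log2 fold change -0.28 ± 0.05) and CYCB1;1 (-0.18 ± 0.04), and the list median was -0.05 (camera adjusted p = 0.157). Among 19 genes of DNA replication and the G1/S step 1 rose, CYCD3;1 (0.22 ± 0.04), and 1 fell, CYCD3;3 (-0.20 ± 0.05), with the same counts adjusted over the list alone (camera adjusted p = 0.259). The calls of all 4 ended without wild type 1 (adjusted p of 0.0537 or more) and without wild type 2 (0.0507 to 0.245), those of CYCB1;1 (0.0538) and CYCD3;3 (0.172) without plt1 plt2 2, and that of CYCB1;1 without plt1 plt2 1 (0.0606). With a replicate block CYCB1;1 (adjusted p = 0.0582) and CYCD3;3 (0.0532) were not called, nor was CYCB1;1 by DESeq2 (0.0813). None of 11 ribosome biogenesis genes was called, by edgeR or adjusted over the list alone, with log2 fold changes of -0.10 for FIB2 and -0.09 for NUC1 (camera adjusted p = 0.709); without plt1 plt2 1 both were called lower (edgeR adjusted p = 0.0264 and 0.0451). AUR2, CYCD3;1, FIB2 and NUC1 overlap other genes, AUR2 and NUC1 on the other strand.

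Markers of other cell types were examined in the same way. Phloem genes had 0 called higher and 3 lower of 7 (0 and 4 adjusted over the list alone), the sieve element genes SEOR2 (log2 fold change -1.69 ± 0.27) and SEOR1 (-1.39 ± 0.27) and the sucrose transporter gene SUC2 (-0.52 ± 0.15). The list was not called (camera adjusted p = 0.0535) but passed without wild type 2 (0.0434) and with a mean of 50 or more reads (0.0421). The calls of SEOR1 ended without wild type 1 (adjusted p = 0.0721) and without wild type 2 (0.0503), and that of SUC2 ended without wild type 1 (0.256), wild type 2 (0.111) or plt1 plt2 2 (0.0512), with a replicate block (0.0595) and by DESeq2 (0.120). None of 8 xylem genes was called, with values of -0.26 for CESA7 and -0.49 for LAC17 (camera adjusted p = 0.361), though LAC17 was called without plt1 plt2 1 (edgeR adjusted p = 0.0273). Of 11 procambium genes CLE44 (0.43 ± 0.05) and PHV (0.29 ± 0.04) rose and 0 fell (camera adjusted p = 0.126), and of 12 epidermis genes PDF2 (-0.36 ± 0.05), PDF1 (-0.32 ± 0.05) and ATML1 (-0.30 ± 0.06) fell and 0 rose (camera adjusted p = 0.356). The PDF1 call ended without wild type 1 (adjusted p = 0.0560) and that of ATML1 without wild type 2 (0.0853). Of 14 endodermis genes only FAR5 was called (0.77 ± 0.14; camera adjusted p = 0.278), a call that ended without wild type 2 (adjusted p = 0.0569). Adjusted over the list alone, the counts of the xylem, procambium, epidermis and endodermis lists were the same. RHD6, the only root hair gene tested, rose from 5.38 to 13.8 CPM (1.36 ± 0.11). CESA7 and LAC17 overlap genes on the other strand, and CLE44 overlaps a gene on its own strand.

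Photosynthesis genes had 0 called higher and 4 lower of 23, with the same counts adjusted over the list alone. These were PSAL (log2 fold change -1.28 ± 0.33), the regulator GLK2 (-1.20 ± 0.20), LHCA4 (-0.40 ± 0.09) and PSBP1 (-0.30 ± 0.08). The list was not called by camera (adjusted p = 0.0901) and was by fry (0.0105). The calls of PSAL (adjusted p = 0.0915), LHCA4 (0.0819) and PSBP1 (0.248) ended without wild type 1, and without wild type 2 the same 3 had 0.245, 0.132 and 0.0771; PSAL (0.104) also ended without plt1 plt2 2, PSBP1 (0.0512) without plt1 plt2 1, and both by DESeq2 (0.0807 and 0.117). LHCA4 and PSBP1 overlap genes on the other strand.

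Hypoxia response genes were called lower in 5 of 10 cases and higher in 0 (7 and 0 adjusted over the list alone). The genes that fell included HRE1 (log2 fold change -0.80 ± 0.16), the cysteine oxidase gene PCO1 (-0.72 ± 0.09), the haemoglobin gene PGB1 (-0.54 ± 0.08) and PDC1, a pyruvate decarboxylase gene (-0.51 ± 0.14). Camera called the list downward (adjusted p = 0.000929), with an adjusted p = 0.425 with an estimated correlation. The HRE1 call ended without wild type 2 (adjusted p = 0.110), and that of PDC1 without wild type 1 (0.171), wild type 2 (0.135) or plt1 plt2 1 (0.0989) and by DESeq2 (0.0535). HRE1 overlaps a gene on the other strand.

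Defence genes of the salicylate and pattern-triggered list rose in 3 of 7 cases and fell in 0 (3 and 1 adjusted over the list alone). FRK1 (log2 fold change 1.14 ± 0.17, overlapping a gene on the other strand), WRKY70 (1.03 ± 0.16, from 4.97 to 10.2 CPM) and the camalexin synthesis gene PAD3 (0.39 ± 0.09) rose. Camera called the list upward (adjusted p = 0.0412), with an adjusted p = 0.575 with an estimated correlation. It was not called without wild type 2 (0.240), without plt1 plt2 1 (0.0567), without a filter (0.104) or by fry (0.148). The PAD3 call ended without wild type 1 (adjusted p = 0.0777) and without wild type 2 (0.124). Of 5 jasmonate and wounding genes AOS fell (-0.79 ± 0.08) and 0 rose (2 fell adjusted over the list alone), and the list was called by fry (adjusted p = 0.0119) and not by camera (0.101). Of 8 heat shock genes HSP17.6II (0.64 ± 0.16) and HSP101 (0.22 ± 0.06) rose and 0 fell (3 and 0 adjusted over the list alone). Both calls ended without wild type 1 (adjusted p = 0.161 and 0.146), without wild type 2 (0.0847 and 0.179) and without plt1 plt2 1 (0.0937 and 0.232), and HSP101 was not called by DESeq2 (0.0584). The heat shock list was not called by camera (adjusted p = 0.0901) except without wild type 2 (0.0448) or plt1 plt2 2 (0.00368). HSP101 overlaps a gene on the other strand.

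Expansin and wall-loosening genes were called downward by camera (adjusted p = 0.0335), with an adjusted p = 0.425 with an estimated correlation, and 0.123 without plt1 plt2 1. Of 9 tested members 1 rose and 2 fell, with the same counts adjusted over the list alone, and the median was -0.06. XTH9, which encodes a xyloglucan endotransglucosylase rather than an expansin, fell from 76.0 to 33.1 CPM (log2 fold change -1.20 ± 0.06), EXPA14 fell (-0.66 ± 0.11) and EXPA4 rose from 764 to 911 CPM (0.25 ± 0.05). The calls of EXPA14 (adjusted p = 0.0501) and EXPA4 (0.0694) ended without wild type 1, and that of EXPA4 also without wild type 2 (0.0685).

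**Figure D4:**
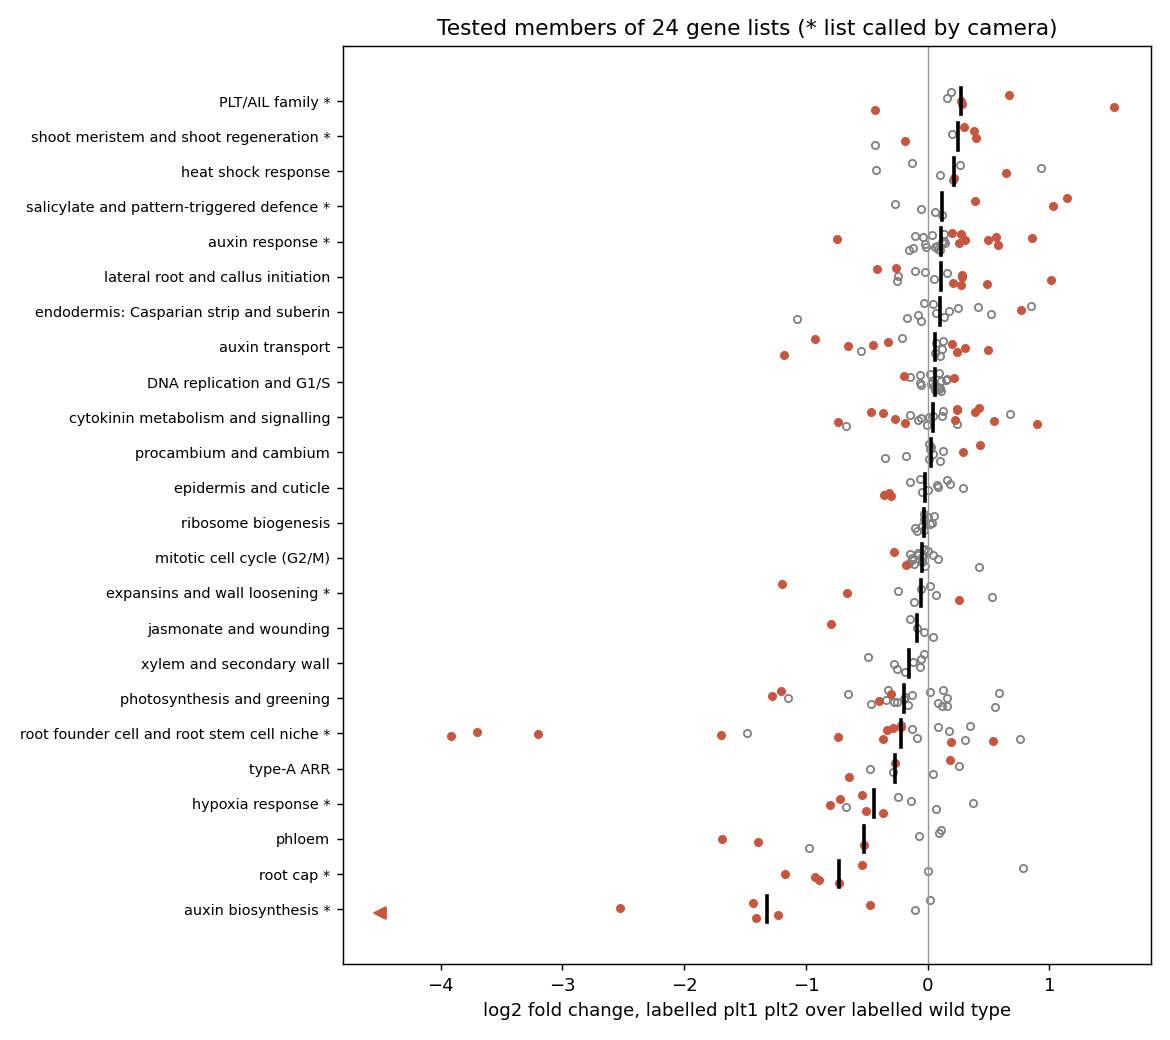
Log2 fold change (horizontal axis, libraries labelled plt1 plt2 over those labelled wild type) of each tested member of the 24 lists, with filled points for called genes, open points for others, a black bar for the list median and a triangle for YUC3, which lies beyond the axis. The auxin biosynthesis median lay at -1.32 and the PLT/AIL median at 0.27; stars mark the 9 lists called by camera, of which 0 were called with an estimated correlation.

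Families of genes were also tested for enrichment among the changed genes. Of 62 tests, 17 passed (one-sided Fisher's exact tests, adjusted). Genes of a family are not independent replicates, and some share sequence, so these p values can be too small. Among the genes that fell, the families with the smallest adjusted p were glutathione S-transferases (11 of 43, adjusted p = 0.00171), led by GSTF9 (log2 fold change -1.36), GSTU16 (-1.02) and GSTF3 (-0.83); pectin methylesterases and pectin lyases (16 of 92, adjusted p = 0.00258), among them PME2 (-1.55), AT3G05620 (-1.96) and AT3G26610, at least 11.9-fold lower with 0 reads under plt1 plt2; receptor-like kinases (31 of 265, adjusted p = 0.00402), among them AT5G41300, at least 34.5-fold lower, AT3G50230 (-3.60) and AT5G41290 (-3.12); and xyloglucan endotransglucosylase/hydrolases (6 of 19, adjusted p = 0.00704), with XTH15 (-1.39), XTH9 and XTH11 (-1.03). These families rest on keywords. AT5G41300 and AT5G41290 are described as receptor-like protein kinase-related and need not encode kinases. AT3G26610 is described as pectin lyase-like and AT3G05620 as of the invertase/pectin methylesterase inhibitor superfamily, so neither need encode the named enzyme. Arabinogalactan proteins (7 of 32, with AGP7 -0.85, FLA15 -0.71 and AGP18 -0.52) and aquaporins (6 of 24, with PIP2E -2.67, RD28 -0.74 and PIP2B -0.72) each had an adjusted p = 0.0194. GDSL lipases (8 of 46, adjusted p = 0.0254) included GLL22 (-1.17), AT1G09390 (-0.94) and AT1G54010 (-0.61).

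Transcription factor families were enriched in both directions. Among the genes that rose were NAC genes (10 of 57, adjusted p = 0.00402; NAC2 0.71, NAC048 0.58 and NAC3 0.52), WRKY genes (8 of 55, adjusted p = 0.0232; WRKY51 1.02, WRKY70 and WRKY59, at 0.0520 against 0.351 CPM), MYB genes (11 of 94, adjusted p = 0.0232; MYB102 2.28, MYB84 1.12 and MYB62 0.97) and descriptions naming Aux/IAA (5 of 22, adjusted p = 0.0223; IAA29, IAA11 and ETT 0.52, the last an auxin response factor). Basic helix-loop-helix genes were enriched among both the genes that rose (10 of 85, adjusted p = 0.0279; KDR 1.15, AT4G37850 0.63 and AT5G56960 0.55) and those that fell (12 of 85, adjusted p = 0.0232; AT1G68240 -3.06, EGL3 -1.84 and SCRM2 -1.34, from 72.4 to 28.5 CPM). Descriptions matching AP2 fell in 11 of 79 cases (adjusted p = 0.0279), but NGA2 (-1.89) and AT4G01580 (-1.46) among them are B3 genes, and without B3 descriptions, chosen after seeing the data, 7 of 59 fell (unadjusted one-sided exact p = 0.0562). Cytochrome P450 genes were enriched among those that rose (13 of 129, adjusted p = 0.0286; CYP71B20 1.32, TT7 1.17 and CYP71B5 0.96) and those that fell (15 of 129, adjusted p = 0.0319; CYP81F4 -2.38, CYP714A2 -2.36 and CYP79B3), and UDP-glycosyltransferases among those that rose (10 of 90, adjusted p = 0.0319; AT2G22590 0.92, UGT84A1 0.67 and UGT74F2 0.66). With calls at an adjusted p below 0.1, MYB (adjusted p = 0.0680) and rising bHLH (0.143) genes and AP2 (0.0505) were no longer enriched, nor were falling P450 genes with DESeq2 calls (0.129).

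Several members named for these families have uncertain counts or calls. Of their exon bases, 86.3% of CYP71B20, 86.1% of AT4G01580, 79.5% of AT5G41290, 60.5% of RD28, 54.9% of PIP2B, 57.6% of GLL22, 54.4% of AT1G54010 and 20.7% of NGA2 lie in matches elsewhere in the genome, and XTH15, CYP81F4, AT1G09390, UGT84A1 and UGT74F2 overlap genes on the other strand and AT5G56960 a gene on its own strand. Leaving out the library labelled wild type 1 or wild type 2 ended the calls of XTH15, AT3G05620, FLA15, CYP71B20, CYP71B5, CYP714A2, WRKY59, WRKY51, MYB102, MYB84, MYB62, KDR, AT4G37850, NGA2, AT1G09390, GSTF3, UGT84A1, UGT74F2 and PIP2E, with adjusted p between 0.0503 (CYP71B20) and 0.248 (NGA2). Of these, DESeq2 did not call AT3G05620 (adjusted p = 0.104), CYP714A2 (0.0908), WRKY59 (0.0533) and MYB84 (0.110), and the call of MYB84 also ended with a replicate block (0.0503). The calls of MYB102 (adjusted p = 0.0958) and MYB84 (0.105) ended without plt1 plt2 1, and those of AT3G05620 (0.107), CYP714A2 (0.0884), WRKY59 (0.0693) and NGA2 (0.0539) without plt1 plt2 2.

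Called genes were not enriched around PLT1 and PLT2. Within 2 Mb of PLT1 or PLT2, 139 of 1413 tested genes were called (9.84%), against 1886 of 17870 other nuclear genes (10.6%), an odds ratio of 0.925 (two-sided Fisher's exact p = 0.417; genes are not independent replicates). Within 1 Mb the share was lower, 55 of 697 genes (odds ratio 0.723, two-sided exact p = 0.0232).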

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

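The crossed pairing, the B3 alternative and the PLT/AIL list without PLT1 and PLT2 were chosen only after the results were seen. The count of called genes stayed within 1.5 times of 2027 with RLE size factors (2078), no filter (2489), a mean of 50 or more reads (1944), DESeq2 (1666), limma-voom (2042), no organelle genes (2050) and an adjusted p below 0.1 (2944); DESeq2 shared 1612 calls with the 2027. An adjusted p below 0.01 gave 1002 and glmTreat against a fold of 1.5 gave 198, both by stricter construction. Leaving out 1 library gave 1068 to 3026 genes, with fewer calls without either library labelled wild type; the cause was not tested. Lists called went from 9 to 0 with an estimated inter-gene correlation (lowest adjusted p = 0.214) and to 7 to 10 with 1 library left out; fry called 9, of which 7 were among the 9. The estimated correlation lay below the preset 0.01 for auxin biosynthesis (-0.141), wall loosening (-0.114), PLT/AIL (-0.031) and auxin response (-0.016). For these lists a higher correlation does not explain the lost call. For the other called lists it lay between 0.089 (hypoxia response) and 0.396 (salicylate list). With an estimated correlation camera also uses only the 2 residual degrees of freedom of the fit. Enriched families numbered 19 with DESeq2 calls and 18 at an adjusted p below 0.1, against 17. Near PLT1 and PLT2 the odds ratio was 0.723 in the 1 Mb window, where the test passed, and 0.957, 1.05 and 0.969 in the 5 Mb window, with DESeq2 calls and with replicate block calls; the cause was not tested. PLT1 stayed between -0.46 and -0.40 and PLT2 between 1.52 and 1.54 on the log2 scale, called throughout. Of 139 called named genes, 82 kept their call without each library in turn, 122 with DESeq2 and 139 with RLE; 0 turned direction.

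The labels' shared replicate numbers do not say that libraries were paired. With a replicate block 1909 genes were called, 1803 of them among the 2027, and the block left the 9 lists called. Deviations of same-numbered libraries from their group means correlated at r = -0.117 across 17177 genes, which are not independent replicates. The crossed pairing called 2340 genes, 1979 of them among the 2027.

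Depth limits genes near the floor of 3 counts, 0.0254 CPM over the libraries labelled plt1 plt2 and 0.0260 CPM over those labelled wild type, and 4597 of 23922 loci were too low to test.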

Other observations

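The tests of an exchange of libraries, of root cap and phloem shares, and of parent lines, the direction of the last included, were chosen after the result they measure was seen. The lists of sugar starvation and glucosinolate genes were added after the largest changes were seen, and their members were picked before their values were looked at. CYP81F4 and GSTF9 of the indole list are also genes named above for their families, so that list is not independent of those results.

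Genes known to rise when plant cells run short of sugar were among the largest increases. ASN1, GAT1_2.1, BCAT-2, SEN1, MIOX4 and AT1G21400 were picked for their increases and had a median log2 fold change of 1.77, and 1.59 and 1.92 without the library labelled plt1 plt2 1 or 2, which decides nothing about single libraries, since these genes were picked for being higher in both. AT1G21400 (1.41) was chosen after its value was seen. Of 19 tested members of a list of other starvation and dark-inducible genes, 7 rose, 2 fell and 10 were not called (edgeR), with a median log2 fold change of 0.13 and a mean of 0.23. BGLU30 rose from 74.9 to 193 CPM (1.37 ± 0.06); DIN9 (0.78), bZIP1 (0.66), the proline dehydrogenase gene ERD5 (0.59) and the lysine degradation gene LKR (0.41) also rose, and GDH1 (-0.38) and STP1 (-0.23) fell. Camera gave p = 5.83e-07 upward for this list, and p = 0.118 with an estimated correlation. A sugar starvation response in the libraries labelled plt1 plt2 is a hypothesis that the first value is in line with, and sugar levels were not measured.

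More indole glucosinolate genes fell than rose. Of 14 tested members of a list that leaves out CYP79B2, CYP79B3 and MYB34, 8 fell, 0 rose and 6 were not called (edgeR), with a median of -0.21. Those that fell were CYP81F4 (-2.38), GSTF9 from 98.3 to 38.2 CPM (-1.36), CYP83B1 from 46.6 to 28.9 CPM (-0.69), CYP81F3 (-0.63), SOT16 (-0.41), SUR1 (-0.30), GGP1 (-0.21) and GSTF10 (-0.20). Camera gave p = 1.59e-11 downward, and p = 0.0729 with an estimated correlation. Of 4 tested aliphatic glucosinolate genes SOT17 fell (-0.84) and 0 rose (camera p = 0.359, and p = 0.450 with an estimated correlation); whether the indole and aliphatic lists differ was not tested. A shift of the indole pathway is a candidate explanation for the camera value of the indole list, found and tested on the same data. That list was not restricted to genes of the indole branch alone, SUR1 and GGP1 included, so the values do not single out that branch. Whether such a shift lies downstream of the 0 reads of MYB34 was not tested.

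PLT2 reads were higher in the libraries labelled plt1 plt2. Reads shared with a near-identical copy in the reference genome are argued against, since 0 matches there with 50 identical bases lay outside PLT2. A copy absent from the reference was not tested. Transcription from a neighbour stays open: the nearest tested genes, UCN (22123 bp upstream) and AT1G51200, had log2 fold changes of at most 0.16, but 4 annotated loci between UCN and PLT2 were not analysed here. An exchange of 1 library of each label is argued against by the gap between labels, 2.85-fold at its narrowest. An exchange of both labels as a whole stays open, because PLT1 was lower (-0.43) under plt1 plt2 but a disruption need not lower mRNA and the allele structures were not given; a transcript raised by an insertion or by loss of feedback in the mutant was not tested.

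Auxin biosynthesis genes were lower in libraries where root cap genes were also lower, while the phloem list was not called. The median of all 7 tested root cap markers (-0.73) lay 0.69 above that of the called auxin biosynthesis genes (-1.42), with a standard error of 1.197. That of all 7 tested phloem markers (-0.52) lay 0.89 above, with a standard error of 1.204. The standard error of these differences is taken from the spread across genes, which are not independent replicates, and not from that between libraries. Most of that error comes from YUC3, at least 104-fold lower while no root cap marker was more than 2.25-fold lower and no phloem marker more than 3.23-fold; without YUC3, a check added after the result was seen, the differences were 0.68 (standard error 0.521) and 0.88 (0.538). YUC3 and YUC8 (-2.52 ± 0.18 SE) fell further than any of these markers, the lowest being FEZ (-1.17 ± 0.13) and SEOR2 (-1.69 ± 0.27). They had the largest falls of the 6 called genes and were picked after their values were seen, so this decides nothing about loss of cells. How far the markers are confined to their cells in this callus was not tested. For all 6 genes, fewer root cap cells or a lower share of phloem cells cannot be told apart from lower expression per cell, because genes and markers are too few. Loss of other cells was not covered by this comparison. The root niche genes MGP (-3.92), RGF3 (-3.70) and RGF1 (-3.20), all of low counts, fell further than YUC8, though the median of their list was -0.22. YUC3 is also among the genes with 0 reads under plt1 plt2, for which another parent line stays open. The genotype remains an open explanation.

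The 13 called genes with 0 reads in both libraries labelled plt1 plt2 lie on 5 chromosomes. Of them 2 (15.4%, exact 95% interval 1.92% to 45.4%) lie within 5 Mb of PLT1 or PLT2, against 15.3% of all tested nuclear genes (one-sided exact binomial p = 0.612). A stretch of another parent line within 5 Mb of either gene thus does not account for most of them. Longer linked stretches were not tested. Another parent line throughout the genome might remove reads of genes that differ from the reference. TIR-NBS-LRR and F-box genes, which vary between accessions, were called in 37 of 332 cases, 27 higher and 10 lower (11.1% against 10.5% of other genes, odds ratio 1.07, two-sided exact p = 0.652; for lower calls alone odds ratio 0.494, 95% interval 0.234 to 0.924, two-sided exact p = 0.0243). These families hold 0 of the 13 genes, so the values decide nothing about them and that explanation stays open.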
